A study of Neurospora crassa with 22 samples.

How the data were processed

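The series holds 22 ChIP-seq samples of Neurospora crassa, and 17 of them, those of CLR-1-GFP, mCherry-tagged CLR-2, XLR-1-GFP and V5-tagged CLR-1, have a deposited table of peaks. Reads were aligned with Bowtie2 per the submitters' processing notes, and peaks were called with MACS per the file headers. Aligner settings, the version of the peak caller and the control it used are not given in the sources used here. Tags per peak are deposited as a count. The score is deposited as the -log10 of the MACS p-value, multiplied by 10 per the file headers. The fold enrichment is the authors' ratio of tags to the local background. The false discovery rate is deposited as a percent, and 1 list has none. Positions are on the NC12 assembly, in base pairs. Total reads per library are not in the files, so no interval or floor was computed. The depth shown is the number of tags per peak, between 10 and 40878.

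The labels gave each sample's group, and the lists of a group were numbered as in the deposited tables. Those tables do not say which library number each list came from. Inputs and mock pulldowns have no peak list and were left out. Peaks outside the 7 chromosomes were left out of all counts of genes and regions. Of the deposited tables, 11 measure the distance to a gene from the peak summit and 5, all CLR-1-GFP on Avicel or sucrose at 4 h, from the peak start, each tested with a tolerance of 3 bp. In those 5 a broad peak can be credited to a gene although its summit lies beside another gene. For XLR-1 on xylan list 2 the gene columns were a copy of those of list 1 (718 of 718 entries), so its genes were taken as the nearest start codon to the peak centre, without regard to strand.

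A target gene is one that the tables name beside a peak in at least 2 lists of a replicated group (both on sucrose), or in the only list of a group with 1. Genes bound by 2 sets were compared with n1*n2/N genes expected by chance and a one-sided Fisher's exact test, with N the 9729 protein-coding genes on the 7 chromosomes. This background was also used for the gene lists. The null for neighbouring genes was 1000 rotations of 1 set along the gene order. Overlap of replicate peak lists, by at least 1 bp, was set against 1000 shuffles of peak positions within chromosomes. p-values of 45 tests of gene lists (9 lists in 5 groups) and of 10 pairs of sets were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. The 9 lists, 75 genes in all, covered cellulose degradation, xylan degradation and pentose use, mannan and pectin degradation, sugar transporters, starch degradation, transcription factors of carbon use, secretion, highly expressed housekeeping genes and the construct genes ccg-1 and his-3. A list of 7 ribosomal protein genes was added after the data were seen.

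The groups, tests, gene lists, alternatives and rule for named genes were fixed before the data were examined. The rule named all members of the fixed lists, the 10 targets of each replicated group with the best median rank by score, and, for each comparison, the 10 best-ranked genes in all lists of 1 group and in no list of the other. Alternatives were a score of at least 100, a fold of at least 5, an FDR of at most 5%, equally long lists (the best-scored peaks of each list, as many as the shortest list compared), membership in all lists or in at least 1, the nearest listed gene only, genes within 1500 bp, overlapping regions in place of genes, other backgrounds, and each list left out in turn. Added after the data were seen were the annotation of every list again from its summits, peaks upstream of genes only, lists without peaks over 5 kb from any gene, and the rotation test. The annotation from summits recovered between 99.4% and 99.9% of the genes of the lists measured from summits. Fold values of named genes come from the peaks assigned by summit, a choice also made after values were seen, and counts of lists are as deposited unless summits are named. The motif test and lists built from product names were not run, since no genome sequence and no product names were at hand.

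The methods were tested on simulated data. With 1000 true genes of which each list kept 80% and 300 other genes per list, the rule of 2 lists in 3 recovered 90.3% of the true genes, and 97.4% of the genes it called were true. The simulated lists were about equally long, with other genes drawn independently for each. Real lists of a group differed in length, as for XLR-1 on Avicel with 1046 to 6365 genes. These rates therefore do not carry over to the real target genes. For unrelated sets of single genes Fisher's test passed in 3.5% of 200 runs, for unrelated sets of neighbouring pairs in 9.5%, and the rotation test in 4%. Shuffles passed in 4% of unrelated peak lists and in all simulated lists that shared peaks. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.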

Results

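The filamentous fungus Neurospora crassa degrades plant cell walls with secreted enzymes, and this needs the regulators CLR-1 and CLR-2, which respond to cellulose, and XLR-1, which responds to xylan. The series asked by ChIP-seq, that is, sequencing of chromatin pulled down with an antibody to a tagged factor, which genes the 3 factors bind directly. Mycelium grown on sucrose was moved to Avicel (crystalline cellulose), xylan or sucrose. CLR-1 and XLR-1 carried GFP and CLR-2 carried mCherry, each behind the ccg-1 promoter, and in 1 further strain CLR-1 carried a V5 tag. The labels write the time after the move as 4 or 24 without a unit, and it is read here as hours from knowledge of the study. Of the 22 samples, 17 had a list of peaks. These were CLR-1 on Avicel (n = 3), CLR-2 on Avicel (n = 3), XLR-1 on Avicel (n = 3), XLR-1 on xylan (n = 3) and CLR-1 on sucrose (n = 2) at 4 h. CLR-1 at 24 h, CLR-2 at 24 h and V5-tagged CLR-1 at 4 h, all on Avicel, had 1 list each and therefore no replicates. The CLR-2 library at 24 h was of another genotype than those at 4 h, a heterokaryon. The other 5 samples, inputs and mock pulldowns from strains with GFP or mCherry alone, had no peak list and were not analysed here.

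The lists held 42691 peaks, between 701 and 8194 each, on the NC12 assembly. Total reads per library were not given, so sequencing depth is unknown. The depth within peaks ran from 10 to 40878 tags. The median per peak was lowest in XLR-1 on Avicel list 2, at 14 tags, and highest in the CLR-2 list at 24 h, at 2898 tags. Scores and fold enrichments are the authors' values for each peak, describe peaks within their own list, and are given below as the lowest to highest over the lists of a group. Within a group at 4 h on Avicel or xylan, between 54.9% and 85.7% of the peaks of the shorter list of each pair overlapped a peak of the other list. In the CLR-2 lists on Avicel, 94.8% of the peaks of list 1 and 33.9% of those of list 3 had a fold below 1. The median FDR of list 2 was 100%. CLR-2 targets are thus genes beside listed peaks, and by fold or FDR not always beside enriched ones. In list 1 fold and score disagreed, with a median fold of 0.5 and a median score of 1359. Its highest fold was 2.39, so CLR-2 results at a fold of at least 5 rest on lists 2 and 3. The sucrose lists overlapped at 36.4%, against 25.4% for shuffled peaks. All 13 pairs of lists gave the smallest p that 1000 shuffles can give (permutation p = 0.000999). Nothing in the labels says that replicates came from separate cultures. All p-values take genes or peaks as the unit, so they describe these gene sets and peak lists and do not measure variation between samples.

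At 4 h on Avicel the question was which genes each factor binds, and cellulase genes stood beside peaks of CLR-1 and CLR-2. The cellobiohydrolase gene cbh-1 (NCU07340, chromosome IV, 4311049 to 4314145) was beside a peak in 3 of 3 CLR-1 lists, with folds of 13.4 to 28.8, and in 3 of 3 CLR-2 lists, with folds of 0.28 to 8.12. All 6 summits lay inside the annotated gene. The cellobiohydrolase gene gh6-3 (NCU07190) and the lytic polysaccharide monooxygenase gene gh61-4 (NCU01050) were likewise listed in 3 of 3 lists of each factor, with CLR-1 folds of 26.2 to 27.7 and 5.16 to 13.6. For the endoglucanase genes gh5-1 (NCU00762) and gh7-1 (NCU05057) the CLR-1 count was 2 of 3 lists as deposited and 3 of 3 by peak summits, with summit folds of 21.7 to 29.1 and 29.0 to 88.0, and the CLR-2 count was 3 of 3. The β-glucosidase gene gh1-1 (NCU00130), whose product splits cellobiose to glucose, was listed in all lists of CLR-1, CLR-2 and XLR-1, on every carbon source tested.

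A target gene was counted when at least 2 of 3 lists named it. Of the 25 cellulose degradation genes, 14 were CLR-1 targets, 3.68 times the number expected by chance (adjusted exact p = 4.27e-05, one-sided Fisher's exact test), and 18 were CLR-2 targets, 5.59 times chance (adjusted exact p = 7.42e-10). XLR-1 had 6 of the 25 as targets on Avicel, 0.896 times chance (adjusted exact p = 1). Monooxygenase genes differed in their lists: gh61-5 (NCU08760) and NCU07898 were in 3 of 3 CLR-2 lists and 1 of 3 CLR-1 lists, and gh61-2 (NCU07760) was in 3 of 3 XLR-1 lists, 2 of 3 CLR-2 lists and no CLR-1 list. Among the 4 mannan and pectin genes, CLR-2 had 3 as targets (5.83 times chance, adjusted exact p = 0.0288), including the mannanase gene NCU08412 and gh2-1 (NCU00890), a β-mannosidase gene, and CLR-1 had NCU08412 alone. That CLR-2 call did not hold without list 1 (adjusted exact p = 0.0523), without list 2 (0.176) or without list 3 (0.424), and it also ended under 5 other settings.

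Xylan genes stood beside XLR-1 peaks. The xylanase genes gh11-2 (NCU07225, chromosome V, 6198659 to 6199980) and gh10-2 (NCU08189), the β-xylosidase gene NCU01900 and the xylulokinase gene xyk-1 (NCU11353) were in 3 of 3 XLR-1 lists on Avicel, with folds of 37.96 to 133, 22.6 to 85.9, 49.3 to 74.7 and 45.7 to 67.5. XLR-1 targets included 10 of the 14 genes of xylan degradation and pentose use, 2.67 times chance (adjusted exact p = 0.00348). CLR-1 had 4 of the 14 (adjusted exact p = 0.360). CLR-2 had 5, among them gh10-1 (NCU05924), gh11-1 (NCU02855) and gh11-2, which missed the threshold (2.78 times chance, adjusted exact p = 0.0828). The CLR-2 call passed in 9 alternatives, including without list 1 (adjusted exact p = 0.00348), list 2 (0.0476) or list 3 (0.00226).

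Sugar transporters and the regulators themselves were also listed. CLR-1 targets held 4 of 6 sugar transporter genes (4.38 times chance, adjusted exact p = 0.0253), among them the cellodextrin transporter genes cdt-1 (NCU00801, folds of 14.9 to 21.7) and cdt-2 (NCU08114, chromosome I, 318873 to 321079, folds of 19.2 to 21.4). This call did not hold when only peaks upstream of a gene counted (adjusted exact p = 0.959) or when 1 list sufficed (0.101). CLR-2 and XLR-1 had 2 of the 6 each on Avicel (adjusted exact p = 0.393 and 0.846). Of 9 transcription factor genes of carbon use, 7 were CLR-1 targets (5.11 times chance, adjusted exact p = 0.000454), 6 were CLR-2 targets (5.18 times, adjusted exact p = 0.00171) and 7 were XLR-1 targets (2.90 times, adjusted exact p = 0.0104). The carbon catabolite repressor gene cre-1 (NCU08807), col-26 (NCU07788) and vib-1 (NCU03725) were targets of all 3 factors. The gene clr-2 (NCU08042, chromosome IV, 4001190 to 4004643) was in 3 of 3 CLR-1 lists, with summit folds of 9.53 to 14.2. Its summits lay upstream in lists 1 and 3, at 3999958 and 3999983, and inside the gene in list 2. For clr-1 (NCU07705) the 3 CLR-2 lists named it 0 times as deposited and 3 times by peak summits. Without CLR-2 list 3 the CLR-2 call for these regulators ended (2 of 9, adjusted exact p = 0.199). It also ended at an FDR of at most 5% (2 of 9, adjusted exact p = 0.216), in all lists (2 of 9, 0.166) and when 1 list sufficed (0.0741). The CLR-2 count was 0 of 9 within 1500 bp and 0 of 9 at a fold of at least 5, and the XLR-1 call on Avicel also ended within 1500 bp, for nearest genes, for equally long lists and when 1 list sufficed.

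**Figure D1:**
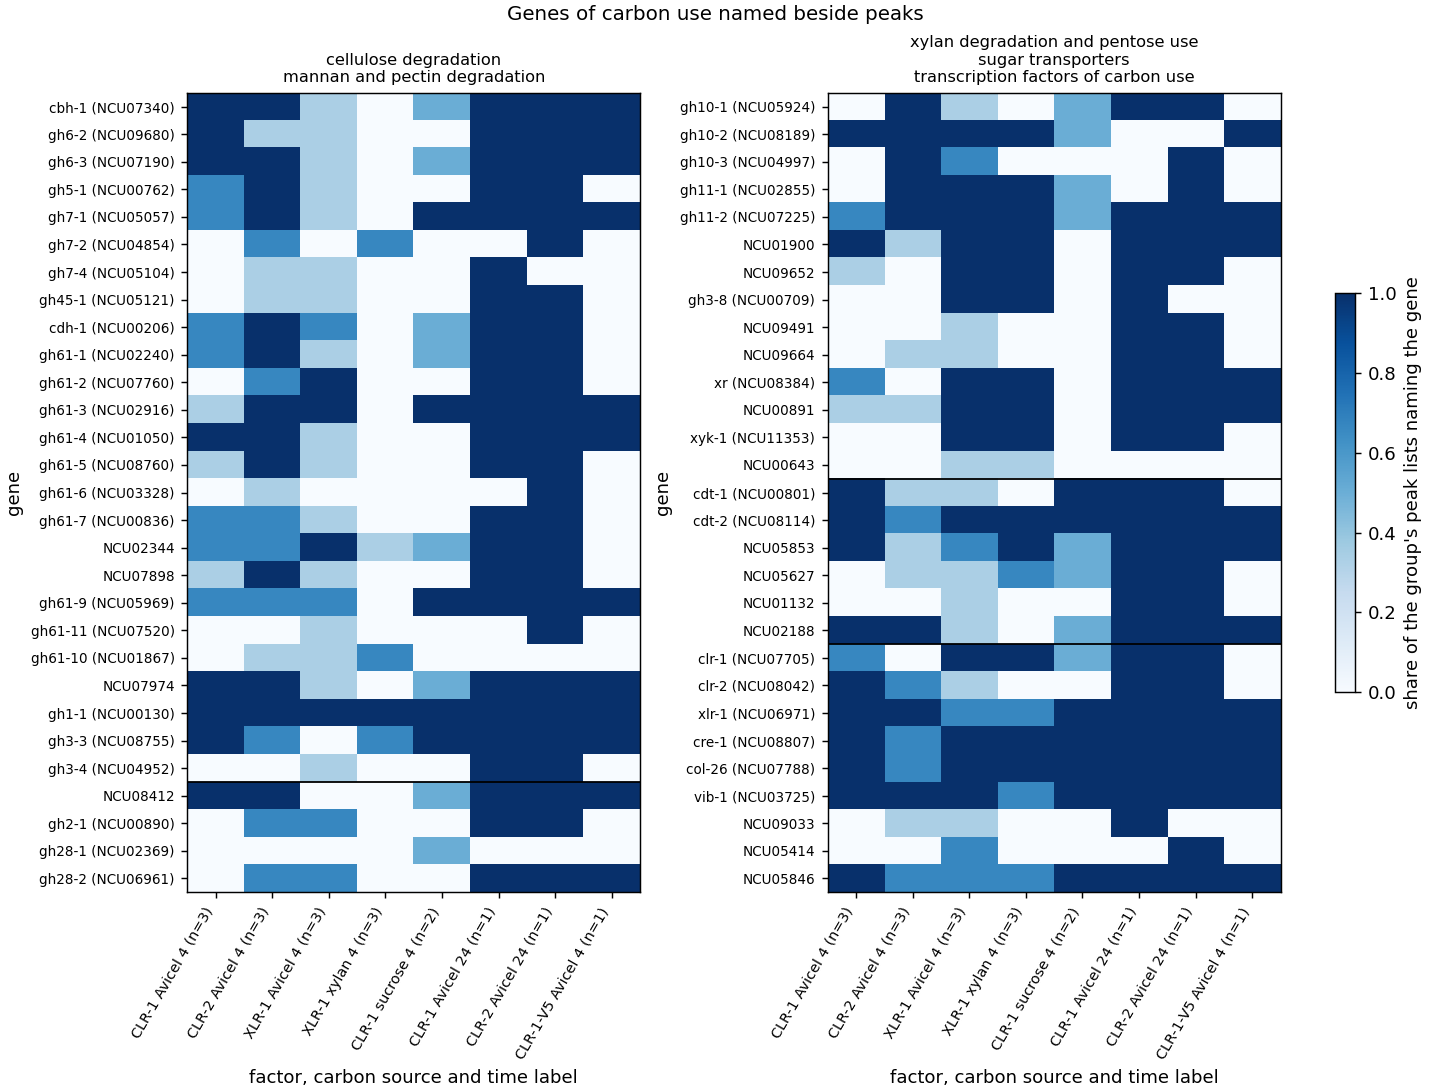
Each cell gives the share of a group's peak lists that name a gene (0 to 1, colour scale), for genes of cellulose, mannan and pectin degradation (left) and of xylan degradation, sugar transport and transcription (right); n is the number of lists. The cellulose genes cbh-1 and gh6-3 are in all 3 lists of CLR-1 and of CLR-2 on Avicel, and xyk-1 is in all 3 lists of XLR-1 on each carbon source and in no CLR-1 or CLR-2 list at 4 h.

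The remaining fixed lists did not pass the threshold in any of the 5 replicated groups. For starch genes the counts were 2, 1, 3, 1 and 0 of 4 for CLR-1, CLR-2 and XLR-1 on Avicel, XLR-1 on xylan and CLR-1 on sucrose, in that order, with the glucoamylase gene gla-1 (NCU01517) a target of the 3 factors on Avicel. Secretion genes gave 0, 1, 2, 0 and 0 of 4, highly expressed housekeeping genes 1, 0, 1, 0 and 0 of 7, and the construct genes ccg-1 and his-3 gave 0 of 2 throughout. By peak summits, however, 4 of the 7 housekeeping genes were CLR-1 targets on Avicel (3.27 times chance, adjusted exact p = 0.0623): act, gpd-1, hH3 and hH4-1. Over all 45 tests 13 passed. Adjusted over the list alone, that is over the 9 gene lists within 1 group, 12 of these passed and cellulose genes on sucrose did not (0.0552). Differences between factors in these counts were not tested.

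The next question was how far the factors share targets. CLR-1 and CLR-2 had 655 target genes in common, 3.44 times the 190.5 expected by chance (p = 1.87e-252, one-sided Fisher's exact test), cbh-1, gh6-3 and gh61-4 among them. CLR-1 and XLR-1 shared 734 (1.85 times chance, exact p = 1.47e-93) and CLR-2 and XLR-1 shared 706 (2.11 times, p = 2.49e-126). All 3 factors had 387 targets in common, against 51.0 expected, including gh1-1, gh10-2, cre-1, col-26 and vib-1. The sets behind these numbers were 1480 genes for CLR-1, 1252 for CLR-2 and 2605 for XLR-1, of the 9729 protein-coding genes. XLR-1 list 3 alone named 6365 genes, so many genes of another XLR-1 list can become targets through its length alone. Rotation of 1 set along the gene order, which keeps neighbouring genes together, gave the smallest p it can for each pair (permutation p = 0.000999).

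These counts moved with single lists. With 1 of 3 lists left out, a target had to be in both others, so each set could only shrink. A fall alone therefore does not show that the targets rest on the list left out. Without list 2 the sets of CLR-1, CLR-2 and XLR-1 were 1232, 1072 and 2451 genes. Without list 1 or list 3, CLR-1 had 723 or 813 targets, CLR-2 had 526 or 468, and XLR-1 had 953 or 929. The genes common to all 3 factors fell to 165 or 145 without CLR-2 list 1 or 3, and to 226 or 240 without XLR-1 list 1 or 3. CLR-1 and CLR-2 shared 351 or 322 genes without CLR-2 list 1 or 3. CLR-1 and XLR-1 shared 406 or 455 without CLR-1 list 1 or 3, and 410 or 416 without XLR-1 list 1 or 3, then 2.83 or 2.94 times chance. CLR-2 and XLR-1 shared 236 or 190 without CLR-2 list 1 or 3 (1.68 or 1.52 times) and 324 or 339 without XLR-1 list 1 or 3. When 1 list sufficed, the overlap was 1.80 times chance for CLR-1 and CLR-2, 1.20 for CLR-1 and XLR-1 and 1.33 for CLR-2 and XLR-1. Equally long lists gave 5.54 and 2.98 times for the pairs with CLR-1, membership in all lists 8.43 and 3.76, and upstream peaks 3.21 for CLR-2 and XLR-1. With peaks of at least 5-fold enrichment, which CLR-2 list 1 lacked, CLR-2 kept 15 genes. Of these 11 were CLR-1 targets, 6.57 times chance, and 3 were XLR-1 targets, 0.747 times chance. Counted as overlapping regions in place of genes, CLR-2 and XLR-1 overlapped 1.14 times chance.

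Genes found in every list of one factor and in none of another were counted for each pair of factors. Between CLR-1 and CLR-2, 92 genes were in all CLR-1 lists and no CLR-2 list, of which 52 were also so by summits. They included the β-glucosidase gene gh3-6 (NCU07487, CLR-1 folds of 24.1 to 30.4) and the poly(ADP-ribose) polymerase gene parp (NCU08852, 21.9 to 30.9). In the other direction there were 50 genes, 44 also by summits, with the xylanase gene gh11-1 among them. CLR-1 had 88 genes against XLR-1 (59 by summits), including the β-glucosidase gene gh3-3 (NCU08755, CLR-1 folds of 18.9 to 20.9) and os-2 (NCU07024), which encodes the MAP kinase of the osmotic stress pathway. XLR-1 had 383 against CLR-1 (341 by summits) and 152 against CLR-2 (125 by summits), and xyk-1 was in both groups. CLR-2 had 100 against XLR-1 (75 by summits), with NCU17048, which lies beside gh6-3, and the mannanase gene NCU08412, each in 1 XLR-1 list by summits. Mixed groupings of the same lists gave more such genes for CLR-1 and CLR-2 (218 against 142) and for CLR-2 and XLR-1 (804 against 252), so these counts do not by themselves set those factors apart. Outside the fixed lists, the glutamine synthetase gene gln-1 (NCU06724) had CLR-1 folds of 27.2 to 111 and was in 3 of 3 lists of CLR-1, CLR-2 and XLR-1.

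XLR-1 was compared between Avicel and xylan at 4 h to see whether its sites depend on the carbon source. The xylan genes were beside XLR-1 peaks on both. On xylan, gh11-2 had folds of 87.3 to 230.2, gh10-2 of 59.1 to 139, the xylose reductase gene xr (NCU08384) of 70.7 to 161.2, the xylitol dehydrogenase gene NCU00891 of 45.9 to 70.2 and cdt-2 of 70.0 to 152, each in 3 of 3 lists. Of the 14 xylan and pentose genes, 9 were targets on xylan (9.43 times chance, adjusted exact p = 9.93e-07), with gh10-2, gh11-1, gh11-2 and xyk-1 also targets on Avicel. Transcription factor genes gave 6 of 9 (9.78 times, adjusted exact p = 7.75e-05), among them clr-1, cre-1 and col-26, but 0 of 9 within 1500 bp. Transporters gave 3 of 6 (7.34 times, adjusted exact p = 0.0243), a call that ended without list 1 (adjusted exact p = 0.0576) or list 3 (0.0642), for scores of at least 100, for nearest genes, within 1500 bp and when 1 list sufficed. Cellulose genes gave 4 of 25 (adjusted exact p = 0.229) and mannan and pectin genes 0 of 4 (adjusted exact p = 1).

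XLR-1 had 663 targets on xylan, and 444 of them were also among its 2605 targets on Avicel (2.50 times chance, p = 4.74e-112, one-sided Fisher's exact test). The overlap was 6.35 times chance for regions in place of genes, 5.23 for scores of at least 100, 5.48 for equally long lists, 4.31 for upstream peaks and 6.59 in all lists, but 1.25 when 1 list sufficed. A further 1898 Avicel targets were in no xylan list, of which 466 were in all 3 Avicel lists, such as the allantoinase gene aln-1 (NCU02296, folds of 11.3 to 20.7) and its neighbour mss4 (NCU02295). Conversely, 65 xylan targets were in no Avicel list, and 12 of these were in all 3 xylan lists. By summits 7 of the 12 held, including hgt-1 (NCU10021, folds of 7.62 to 20.7), stk-41 (NCU06421) and NCU05448. With the 701 best-scored peaks of each list the Avicel set fell to 670 genes against 570 on xylan, and the Avicel genes in no xylan list to 377, while the genes on xylan alone rose to 232.

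This difference moved with single lists. Leaving out a list of 1 carbon source could only shrink its own set and only add genes found on the other alone. Without Avicel list 2 the genes in no xylan list were 1842. Without Avicel list 1 or 3 the genes in no xylan list fell to 514 or 474, the Avicel set to 953 or 929, and the overlap rose to 4.62 or 5.01 times chance. Without xylan list 1 or 3 the xylan set fell to 340 or 360, and its genes in common with Avicel to 229 or 279. The 65 genes in no Avicel list became 28, 43 or 18 without xylan list 1, 2 or 3, and 184 without Avicel list 3. Summits of XLR-1 lay inside annotated genes for 77.8%, 62.7% and 83.4% of the peaks of the Avicel lists and for 28.3%, 32.7% and 20.7% in the xylan lists. Among the 701 best-scored peaks of each list these shares were 73.1%, 58.2% and 84.5% on Avicel and 27.1%, 33.2% and 20.7% on xylan, and with 3 lists a side the smallest two-sided exact p is 0.1.

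**Figure D2:**
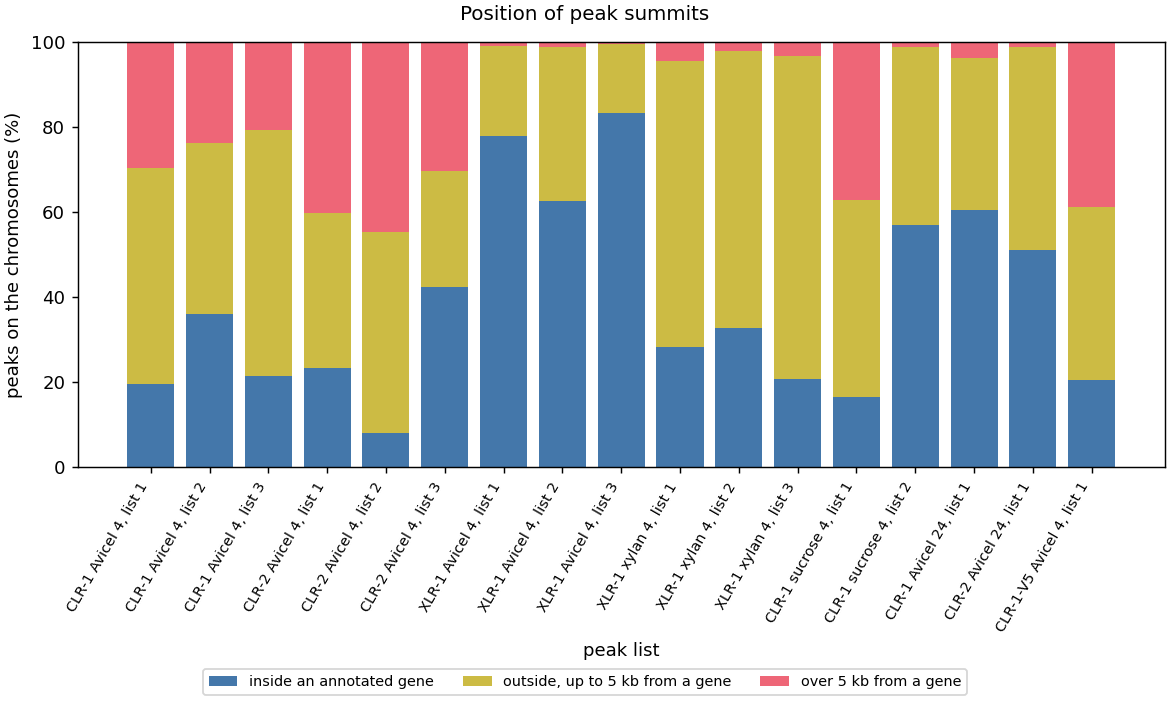
Share of each list's peaks on the 7 chromosomes (%, stacked bars) with a summit inside an annotated gene, outside but up to 5 kb from one, or over 5 kb from any gene. The 3 XLR-1 lists on Avicel have between 62.7% and 83.4% of summits inside genes, and the 3 on xylan between 20.7% and 32.7%.

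CLR-1 was compared between Avicel and sucrose, a carbon source on which cellulases are not made, to ask whether it is on its target genes without an inducer. The β-glucosidase genes gh1-1 and gh3-3 and the transporter genes cdt-1 and cdt-2 were in both sucrose lists, as were xlr-1 (NCU06971), cre-1 and NCU05846, known as clr-3. The endoglucanase gene gh7-1 was in both sucrose lists, with folds of 16.3 and 3.90. The regulator clr-2 and the cellobiohydrolase gene gh6-2 (NCU09680, chromosome V, 858215 to 859731, Avicel folds of 9.22 to 19.0) were in 3 of 3 Avicel lists and in no sucrose list, and the same was so of the β-xylosidase gene NCU01900. The gene cbh-1 was in 1 of 2 sucrose lists, with a fold of 4.08. Both sucrose lists, and all 3 Avicel lists, had peaks on either side of clr-2, on sucrose with summits at 3997608 and 3997626 before NCU16830, the gene upstream of clr-2, and at 4006765 and 4006797 before NCU08043 past its 3' end. NCU16830 and NCU08043 were chosen after their values were seen. Of the 25 cellulose genes, 5 were targets on sucrose (3.50 times chance, adjusted exact p = 0.0425), and by summits 7 were (adjusted exact p = 0.0102). The call ended without sucrose list 1 (adjusted exact p = 0.497), for scores of at least 100, for nearest genes, for upstream peaks only, when 1 list sufficed and against the background of named genes. Transcription factor genes gave 5 of 9 (9.72 times, adjusted exact p = 0.000467), a call that ended within 1500 bp (adjusted exact p = 0.0797) and when 1 list sufficed (0.0867). Transporters gave 2 of 6 (adjusted exact p = 0.126). By summits 3 of the 6 were targets (adjusted exact p = 0.0301), and without sucrose list 2 the call also passed (4 of 6, adjusted exact p = 0.00837). Xylan genes gave 0 of 14 and mannan and pectin genes 0 of 4 (adjusted exact p = 1 for each).

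Of 556 genes in both sucrose lists, 500 were also CLR-1 targets on Avicel, 5.91 times the 84.6 expected (one-sided Fisher's exact test, -log10 p of 369.9). A further 280 Avicel targets were in no sucrose list, and 52 of these were in all 3 Avicel lists. Only 18 genes were in both sucrose lists and in no Avicel list, and by summits 8 of the 18 held. With 1 sucrose list left out, every gene of the other list counted, 2328 without list 1 and 1047 without list 2. Values without a sucrose list therefore come from a looser rule than the main ones. The shared genes were 808 or 892 without sucrose list 1 or 2, in the first case 2.28 times chance, and 305 or 300 without Avicel list 1 or 3. The overlap was 2.33 times chance when 1 list sufficed and 11.8 times within 1500 bp. The 280 genes became 77, 154 or 153 without Avicel list 1, 2 or 3, and 672 or 588 without sucrose list 1 or 2. The 18 became 1166 or 49 without sucrose list 1 or 2, and 46 without Avicel list 3. The median FDR of sucrose list 2 was 17.7%, and at an FDR of at most 5% the sucrose set was 124 genes and the genes in no sucrose list were 572.

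**Figure D3:**
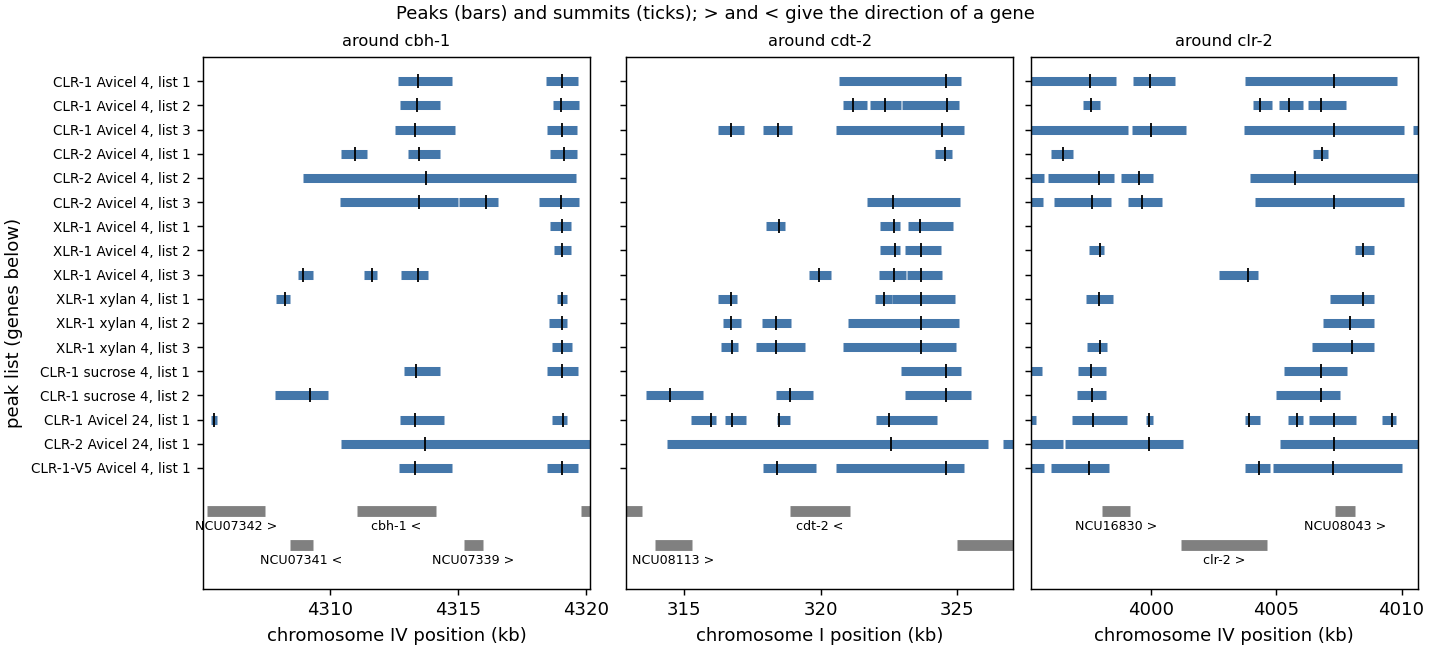
Peaks (bars) and summits (ticks) of all 17 lists around cbh-1, cdt-2 and clr-2 (x axis, NC12 position in kb on chromosomes IV, I and IV), with annotated genes in grey and their direction. Upstream of clr-2, CLR-1 summits on Avicel lie at 3999958 and 3999983 in lists 1 and 3, and the peaks past its 3' end have summits at 4006765 and 4006797 in the sucrose lists.

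The 24 h lists asked whether binding on Avicel lasts, with 1 list per factor. The CLR-2 list at 24 h named 23 of the 25 cellulose genes, among them cbh-1, gh6-2, gh6-3 and gh7-1, and 11 of the 14 xylan and pentose genes, against 5.45 and 3.05 expected by chance. The CLR-1 list at 24 h named 6300 genes, and its 21 cellulose genes and 10 xylan and pentose genes compare with 16.2 and 9.07 expected. Of the 1480 CLR-1 targets at 4 h, 1291 were in that list, 1.35 times chance (p = 2.26e-98, one-sided Fisher's exact test), where a list so long allows 1.54 at most and so says little about lasting binding. With equally long lists the overlap was 2.35 times chance, and without CLR-1 list 1 or 3 at 4 h the shared genes were 641 or 691. For CLR-2, 485 of 1252 targets were among the 2122 genes at 24 h (1.78 times chance, exact p = 8.98e-49). Without CLR-2 list 1 or 3 at 4 h the shared genes were 286 or 216. The CLR-2 overlap was 2.84 times chance, for 74 genes, at an FDR of at most 5%, and the median FDR of the CLR-2 list at 24 h was 51.2%. At a fold of at least 5 it was 49.9 times, for 15 genes, but as regions in place of genes it was 372 regions, 0.624 times chance. No test of a change with time could be made with 1 list. For CLR-2 the genotype also differed between 4 and 24 h, so time and genotype cannot be told apart.

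The V5-tagged CLR-1 at 4 h on Avicel tested whether sites depend on the GFP construct. Its list named gh1-1, gh3-3, gh6-2, gh6-3, cbh-1 and cdt-2, and 10 of the 25 cellulose genes. Of its 1011 genes, 796 were CLR-1-GFP targets (5.18 times the 154 expected, -log10 p of 535), 667 were CLR-2 targets (5.13 times, -log10 p of 410.2) and 278 were XLR-1 targets on xylan (4.04 times, p = 4.44e-110, one-sided Fisher's exact tests). Within 1500 bp the overlap was 7.82 times chance with CLR-1-GFP and 8.17 times with CLR-2. For genes in all CLR-1-GFP lists it was 7.98 times. The V5 list had 278 genes in common with CLR-1-GFP and not CLR-2, 149 with CLR-2 and not CLR-1-GFP, 518 with both and 66 with neither. The label gives the antibody of this library as none, and if none was used the list is not a CLR-1 pulldown and these overlaps do not bear on the GFP construct.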

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

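The counts in this part were chosen only after the peaks had been seen, and no control list was at hand to set them against. Peaks outside the 7 chromosomes, which no comparison used, drew attention because they carried many tags. Of the 17 lists, 9 had peaks on the same contig, named Supercontig_10.21, whose nature the labels do not give. In CLR-1-GFP on Avicel list 2 a single peak there, from 3 to 51110, held 15351 tags, the highest count of any peak in that list. No explanation was tested.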

How the results depend on the processing

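The alternatives chosen only after the data were seen were annotation from summits, upstream peaks only, removal of far peaks and the rotation test. Values past the threshold held their direction except those named as reversed here, and unless stated the cause was not tested. List values that had not passed crossed chance more freely: from summits, housekeeping genes went from 0.939 to 3.27 times in CLR-1 on Avicel and from 0 to 3.76 times on sucrose, mannan and pectin genes on sucrose from 0 to 3.29, and the construct genes from 0 to 3.04 in CLR-2 and 1.53 in XLR-1 on Avicel, none past the threshold. Calls for cellulose genes in CLR-1 and CLR-2 on Avicel, xylan genes in XLR-1 on each carbon source and transcription factor genes in CLR-1 on Avicel stayed past the threshold in all 26 alternatives run. Many of these left out a list of another group, which cannot change the group's own target genes and alters only the adjustment. The FDR limit also left the number of CLR-1 targets on Avicel and of XLR-1 targets unchanged. Median overlap of replicate lists was 68.2%, with 55.5% when at least 50% of the shorter peak had to overlap and 48.2% for summits within 200 bp. Of 219 calls for named genes, 140 were kept within 1500 bp, 146 at a fold of at least 5, 173 from upstream peaks, 176 for nearest genes, 189 by FDR, 193 by score, 210 from summits and 219 without far peaks. Across single genes and lists, 338 values fell short of the threshold under an alternative, 12 passed that had not, and 2560 kept their side. The depth of the libraries is unknown, so what it limits could not be assessed. No paired analysis was possible because the list numbers do not pair samples across groups. The motif windows were not run for want of a genome, and a fold of at least 5 gave no value for sucrose because list 2 on sucrose reached 3.92 at most. CLR-2 list 1 on Avicel reached 2.39 at most, so CLR-2 values at that fold rest on lists 2 and 3.

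Target genes within 1500 bp numbered 742 for CLR-1, 584 for CLR-2 and 1682 for XLR-1 on Avicel, 369 for XLR-1 on xylan and 216 for CLR-1 on sucrose. In all lists they numbered 644, 407, 864 and 246 for the first 4 of these groups, and in at least 1 list 2403, 3568, 6541, 1309 and 2819 for the 5. Lists shortened to the shortest of their own group gave 653 for CLR-2 (1920 peaks) and 924 for XLR-1 on Avicel (930 peaks), where shorter lists are the construction itself. A score of at least 100 gave 981 for XLR-1 on Avicel and 330 on xylan. An FDR of at most 5% gave 508 for CLR-2 and 124 on sucrose, a fold of at least 5 gave 15 for CLR-2, upstream peaks gave 1238 for XLR-1 on Avicel, and nearest genes gave 355 on sucrose. With 1 list left out the ranges were 723 to 1232, 468 to 1072, 929 to 2451, 340 to 455 and 1047 to 2328. The last range gives all genes of a single sucrose list.

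Targets of all 3 factors numbered 158 by score, 2 by fold, 215 by FDR, 241 for nearest genes, 110 within 1500 bp, 582 from summits, 215 from upstream peaks, 61 for equally long lists, 59 in all lists, 1387 in at least 1 list and 248 without genes bound on sucrose, and 145 to 353 with 1 list left out. Across groups, equally long means as long as the shortest list compared, 701 peaks for XLR-1. XLR-1 genes on Avicel and in no xylan list numbered 694 by score, 810 from upstream peaks, 377 for equally long lists, 466 in all lists and 5440 in at least 1, with 474 to 2058 with 1 list left out. On xylan and in no Avicel list they numbered 108 from upstream peaks, 232 for equally long lists, 12 in all lists and 208 in at least 1, with 18 to 184 with 1 list left out. CLR-1 genes on Avicel and in no sucrose list numbered 572 by FDR, 52 in all lists and 781 in at least 1, with 77 to 672 with 1 list left out. On sucrose and in no Avicel list they numbered 2 by FDR, 10 for nearest genes, 6 within 1500 bp, 11 from upstream peaks and 1197 in at least 1 list, with 22 to 1166 with 1 list left out. List tests passing numbered 8 within 1500 bp and 6 when 1 list sufficed, and 12 to 14 with 1 list left out.

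The overlap of CLR-2 and XLR-1 turned to 0.747 times chance at a fold of at least 5, where 3 shared genes were left, and that of CLR-2 at 4 and 24 h to 0.624 times for regions. Transcription factor genes numbered 0 in CLR-2 at a fold of at least 5 and 0 within 1500 bp, and 0 in XLR-1 on xylan within 1500 bp.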

Other observations

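The tests of peaks inside transcribed genes, of far peaks in the CLR-1 lists on Avicel alone, and of V5 summits with each peak counted once and lists of CLR-1-GFP and CLR-2 held out, were chosen only after the result was seen. Some of the best-ranked XLR-1 peaks, within and beyond the fixed lists, lay between divergent genes, and how often this was so was not counted. NCU04401 and NCU10110 on chromosome IV shared a peak with folds of 29.2 to 104 on Avicel and 80.4 to 190.2 on xylan, the xylitol dehydrogenase gene NCU00891 shared one with met-6 (NCU00892), and cdt-2 shared one with the mismatch repair gene msh3 (NCU08115). NCU06138 (folds of 22.6 to 79.7 on Avicel, 76.7 to 169 on xylan) was in 3 of 3 XLR-1 lists on each carbon source, in 2 of 3 CLR-1 lists and in no CLR-2 list at 4 h. Of the best-ranked CLR-1 genes, NCU02485 had folds of 25.6 to 35.9 and NCU05058, which lies beside gh7-1, had 29.0 to 88.0. Among the best-ranked CLR-2 genes on Avicel, NCU08411 and the mannanase gene NCU08412 shared a peak with folds of 0.97 to 13.3.

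Ribosomal protein genes, added as a group with high expression, gave 0 of 7 targets for CLR-1, CLR-2 and CLR-1 on sucrose, 0 of 7 for XLR-1 on xylan, 2 of 7 for XLR-1 on Avicel, and 5, 1 and 0 of 7 in the lists of CLR-1 at 24 h, CLR-2 at 24 h and V5-tagged CLR-1 (adjusted p = 1 for each, one-sided Fisher's exact test). The sucrose lists differed in where peaks fell: summits over 5 kb from any gene made up 37.1% of list 1 and 1.04% of list 2.

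Peaks over 5 kb from any gene made up 20.6% to 29.7% of the CLR-1 lists and 30.3% to 44.5% of the CLR-2 lists on Avicel at 4 h, against 11.5% of the genome. In the CLR-1 lists on Avicel far peaks were weaker, since they scored at or above near ones in 0 of 3 lists and reached their fold in 0 of 3. Their median score percentiles within lists 1, 2 and 3 were 40.4, 38.8 and 31.9, so they were not only the lowest-scored peaks. A lower rank does not by itself show that they are weak peaks near the calling threshold. Over all 8 replicated CLR lists this stays open: the bound set in advance, a score at or above that of near peaks in more than 50% of the lists, was met in 5 of 8, but it left out the fold, which was lower for far peaks in 6 of 8, and it pooled groups that go opposite ways. A signal that depends on neither factor nor tag could also account for them. Of 469 far CLR-1 regions, 92.1% overlapped a CLR-2 region, against 40.7% of near regions. Peaks of V5-tagged CLR-1 met 71.6% of them (51.1% of near regions) and peaks of sucrose list 1 met 65.9% (56.9% of near regions). In the other direction, 28.2% of 1456 far CLR-2 regions overlapped a CLR-1 region, against 34.4% of near ones. Regions found in both sucrose lists met 3.20% of far CLR-1 regions and 35.2% of near ones. Set size limited both of these results: CLR-1 had 469 far regions for the 1456 of CLR-2, and the regions in both sucrose lists included 14 far ones. They therefore do not count against such a signal. Against it stand far CLR-1 shares of 2.35% to 3.84% in the XLR-1 lists, 4.48% in sucrose list 2, 20.3% in CLR-1 at 24 h and 3.41% in CLR-2 at 24 h. The control used for peak calling is, however, not given and could have removed such signal from some lists. A signal of this kind and joint binding of CLR-1 and CLR-2 therefore cannot be told apart.

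XLR-1 had 3.93 times as many target genes on Avicel as on xylan. Counting only genes with a peak upstream of them gave a ratio of 2.36. Such a peak can still lie inside a neighbouring gene, so this ratio does not decide whether peaks inside transcribed genes are the cause. The 701 best-scored peaks of each list brought the ratio to 1.18 (670 against 570 genes), but lists of that length name similar numbers of genes to begin with, 1.35 times as many on Avicel. Longer lists as a technical cause and wider binding of XLR-1 on Avicel therefore cannot be told apart. Of the 10 splits of the 6 lists, 1, the real one, set as many as 1963 genes apart, against 1560 in the highest other split, and 10 splits are too few for a share under 0.05.

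V5-tagged CLR-1 overlapped CLR-2 targets about as far beyond chance (5.13 times) as CLR-1-GFP targets (5.18 times). Shared far peaks are argued against as the reason, since without them the V5 genes found with CLR-1-GFP alone fell from 1.87 to 1.38 times those found with CLR-2 alone (271 against 196), towards CLR-2. The test covered 215 of the 1528 V5 peaks, each counted once, at which the CLR-1-GFP and CLR-2 summits lay over 200 bp apart. The V5 summit was nearer to the CLR-2 summit at 78 and nearer to the CLR-1-GFP summit at 137 (two-sided exact sign test, p = 6.93e-05). No limit was set on these distances. At cdt-1 the V5 summit lay 1 bp from the CLR-1-GFP summit and 273 bp from the CLR-2 summit. At NCU08696 it lay 104302 and 107834 bp away. Nearer therefore need not mean at the same site, and the p-value does not measure how often summits coincide. Against 2 lists of each factor, 37.9% of V5 peaks on average were nearer to CLR-2, below the 46.4%, 55.8% and 43.3% of CLR-2 lists held out and within the 28.3%, 45.1% and 33.6% of CLR-1-GFP lists held out, but single values overlapped (up to 44.0% for V5, down to 40.7% for CLR-2) and 2 of 3 CLR-2 lists fell nearer to CLR-1-GFP themselves, so whether the V5 library holds CLR-2 sites, through a mixed-up label or joint binding, stays open. The label gives its antibody as none, the library is a single list, and no biological explanation was tested.

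For the factor comparisons on Avicel the 10 splits of 6 lists are likewise too few for a share under 0.05. The real split of CLR-1 and CLR-2 set 142 genes apart and the highest other 218, and 2 splits gave as many. For CLR-1 and XLR-1 the real value was 471, the highest other 248, and 1 split gave as many. For CLR-2 and XLR-1 the real value was 252, the highest other 804, and 2 splits gave as many. The split with 804 put the CLR-2 lists 1 and 2 with XLR-1 list 2, which named 1446, 696 and 1046 genes. On the other side were CLR-2 list 3 and XLR-1 lists 1 and 3, with 3085, 2599 and 6365 genes. It thus set short lists against long ones, and whether length alone gives the count was not tested.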
